A study of Mus musculus with 24 samples.

How the data were processed

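The series holds bulk RNA-seq of sorted tumour-infiltrating T cells from mice bearing B16F10-OVA tumours, a mouse melanoma line that carries ovalbumin as a model antigen. Per the labels' protocols, mice received 200 micrograms of an isotype control antibody, an antibody to PD-1 or an antibody to JAML, tumours were taken 1 day later, and CD4+FOXP3+ regulatory T (Treg) cells and CD8+ T cells were sorted into lysis buffer. Libraries were made by the Smart-seq2 protocol for small samples, which amplifies polyadenylated RNA over the whole transcript, from fewer than 400 cells each. Group and replicate number came from the labels alone, giving 6 groups of 4 libraries. The labels do not say that the 4 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be partly technical.

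The authors deposited a table of counts, whole numbers of reads per gene and library without normalization, and this was the only unit used. Per the submitters' processing notes, fastp 0.20.1, STAR 2.7.3a, SAMtools and deepTools 3.3.1 were used with the mm10 build, without a stated role or order. The counting tool, its strand setting and the annotation release are not given in the sources used here, so genes that share sequence with a near-identical copy or overlap another gene are uncertain. The authors' table of TPM, a length-scaled unit, for the same libraries was not used, because it keeps no depth. The count table had 54957 gene rows, of which 26497 had a count in any library and 0 named no gene; 54209 of the IDs (98.64%) occur with the same version in GENCODE mouse release M21, from which positions in mm10 were taken. Gene symbols came from the count table itself.

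Counts were analysed in R 4.3.3. The main test was the quasi-likelihood F test of edgeR 4.0.16 with robust dispersion, TMM normalization, and filterByExpr with a minimum count of 10 and a minimum total of 15. Adjusted p-values are Benjamini-Hochberg values over all genes tested in a comparison, two-sided, with a threshold of 0.05. All 12 libraries of a population entered the fit of an antibody comparison. The 8 isotype libraries entered the comparison of CD8 with Treg cells, and all 24 entered the tests of whether an antibody effect differed between populations (interaction terms). Log2 fold changes are given with their standard errors (SE), and levels as CPM (counts scaled to a common library size) with the SD of 4 libraries. For a gene with 0 counts in a whole group, the fold is a lower bound against a floor of 3 counts over that group, which covers counting error only. Amplified reads without molecular identifiers are not independent molecules.

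Gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. A list needed at least 3 tested members. Camera with an estimated correlation, adjusted in the same way, fry and a two-sided exact permutation test of list scores served as further tests; a list score is the mean log2 CPM of its members with a prior count of 2, and for 4 libraries against 4 the smallest p a permutation can give is 0.0286. The lists were effector and cytotoxicity, inhibitory receptors and exhaustion, tissue residency, naive, memory and stem-like, early T-cell receptor response, MAPK feedback, NF-kB targets, proliferation, type I interferon response, interferon gamma response, Treg signature, CD8 lineage, CD4 lineage and helper, trafficking receptors, glycolysis, oxidative phosphorylation, unfolded protein response, heat shock and handling stress, apoptosis and survival, ribosomal proteins and mitochondrially encoded genes. Lists of markers of other cells covered melanoma, macrophages and monocytes, dendritic cells, B and plasma cells, NK cells, neutrophils, gamma-delta T cells, stroma and endothelium, and erythroid cells. The ribosomal list was taken by symbol and so holds some genes that are not structural, such as Rps19bp1. The neutrophil list never had 3 tested members and was not tested.

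The named genes were chosen by rule. In each comparison they were Jaml and Pdcd1; the 10 genes with the smallest p in each direction among those past the threshold, or where fewer than 3 passed, the 3 with the smallest p, leaving out predicted, clone-named and pseudogene symbols; and up to 4 members with the smallest p from each list past the threshold and from the effector, inhibitory, residency, early receptor response, proliferation and Treg signature lists in any case. Cd8a, Cd8b1, Cd4 and Foxp3 were added for CD8 against Treg cells. One gene chosen by the rule is not reported here, and others were left out for length. Other cell markers given as CPM were chosen after the values were seen. The groups, tests, lists, naming rule and a first set of alternatives were chosen before the data were examined. These alternatives were DESeq2 1.42.0, RLE normalization, no filter on low counts, the replicate number as a block, limma's voomWithQualityWeights, the compared groups alone in the fit (all 24 libraries for CD8 against Treg cells), leaving out receptor segment genes, leaving out libraries below 25% of the median total, and leaving out each library in turn. Alternatives chosen after seeing the data were leaving out the libraries that stood apart, leaving out the pair of Treg libraries highest in Lyz2, the log2 number of genes detected as a covariate, and counting lists by the exact permutation test.

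Replicates were checked for repeated deposits: over 36 pairs within groups, 0 were identical and the lowest chi-square per degree of freedom was 24.2, far above sampling noise. The test steps were tested on simulated data, with 200 genes changed in counts drawn from the real means and library sizes. For CD8 anti-JAML against isotype (11936 genes run), 55 of 100 genes changed 4-fold and 14 of 100 changed 2-fold were recovered, with 5 false calls; members of the naive, memory and stem-like list were raised there too, and calls among them are left out of these numbers. For CD8 anti-PD-1 against isotype (11926 genes), the numbers were 64, 12 and 6. For Treg anti-JAML against isotype (12123 genes) they were 45, 10 and 3, and for Treg anti-PD-1 against isotype (12107 genes) 53, 7 and 1. For CD8 against Treg cells (11005 genes) they were 44, 14 and 2, and for the anti-JAML interaction (13790 genes) 27, 2 and 0. At this sample size, 2-fold changes were therefore mostly missed. The single-cell data named in the series' design text were not analysed here.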

Results

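RNA was measured in 24 libraries of T cells sorted from B16F10-OVA tumours, 4 for each of 6 groups. The groups were CD8 T cells and CD4+FOXP3+ Treg cells taken 1 day after 200 micrograms of isotype, anti-PD-1 or anti-JAML antibody. PD-1 is an inhibitory receptor of activated T cells, and JAML is an adhesion receptor of the junctional adhesion molecule family found on lymphocytes and myeloid cells. Total counts lay between 11170918 and 22556460 per library, with a median of 16238787. In order of replicate number, Treg totals were 20302651, 22556460, 16835821 and 13911087 after isotype. They were 13907913, 11920543, 14617582 and 16234577 after anti-PD-1, and 14859344, 16523768, 19299446 and 16447204 after anti-JAML. CD8 totals were 11727419, 12944316, 15541371 and 16977824 after isotype. They were 15183290, 17106884, 18490887 and 16756767 after anti-PD-1, and 16242997, 11170918, 16456010 and 14385157 after anti-JAML.

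The first principal component of log2 CPM (17.96% of variance) parted the populations, with CD8 libraries between 32.6 and 88.6 and Treg libraries between -98.2 and -41.8. The number of genes detected moved with the antibody in Treg libraries. It was 13264 ± 763 after isotype, 14720 ± 500 after anti-PD-1 and 14372 ± 720 after anti-JAML (mean ± SD, n = 4). In CD8 libraries it was 14095 ± 210, 14841 ± 394 and 14062 ± 550. CD8 anti-JAML library 4 had 6.89% of its counts in mitochondrially encoded genes. CD8 anti-JAML library 2 held 416 CPM of the macrophage gene Lyz2 and 249 CPM of the haemoglobin gene Hbb-bs. Treg isotype library 3 had the highest second component of the 24 libraries, 126.5. In Treg cells Lyz2 stood at 413 ± 424 CPM after anti-PD-1, carried by libraries 1 (647) and 4 (889). It stood at 10.6 ± 9.5 CPM after isotype and 17.9 ± 16.5 after anti-JAML. The comparisons that follow share libraries, so they are not independent of each other.

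**Figure D1:**
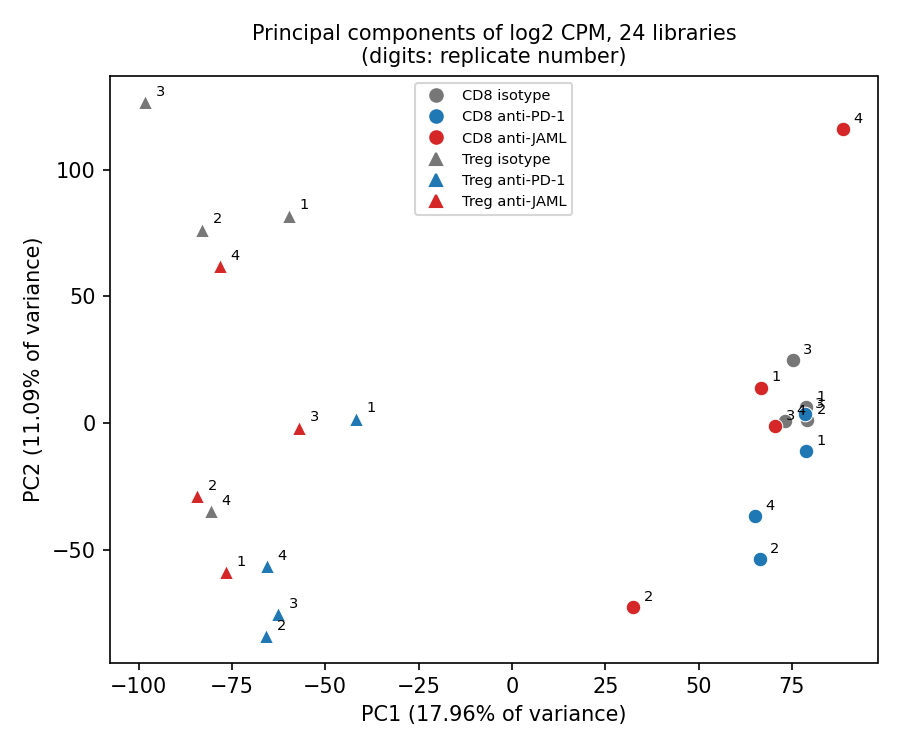
Libraries on the first (x axis, 17.96% of variance) and second (y axis, 11.09%) principal components of log2 CPM, with circles for CD8 and triangles for Treg libraries, colours for the antibody and digits for the replicate number. CD8 anti-JAML library 4 and Treg isotype library 3 reach 116 and 126.5 on the second.

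The genes of the antibody targets were examined first. Jaml (ENSMUSG00000048534.7) is a protein-coding gene on the plus strand of mm10 chromosome 9, from 45079183 to 45108534. Pdcd1 (ENSMUSG00000026285.7), which encodes PD-1, lies on the minus strand of chromosome 1, from 94038305 to 94052553. Jaml was read in every CD8 library, with 10.4 ± 7.01 CPM after isotype, 46.1 ± 16.4 after anti-PD-1 and 33.2 ± 24.99 after anti-JAML (SD, n = 4). In Treg cells Jaml was low, with 2.76 ± 1.01 CPM after anti-PD-1, and near the limit of reading after isotype (0.207 ± 0.415) and anti-JAML (0.0527 ± 0.105). Pdcd1 was abundant in both populations. Its levels after isotype, anti-PD-1 and anti-JAML were 789 ± 129, 978 ± 363 and 586 ± 207 CPM in CD8 cells and 693 ± 231, 834 ± 206 and 707 ± 268 CPM in Treg cells. No antibody comparison moved either gene past the threshold in edgeR. The log2 fold change of Jaml in CD8 cells was 1.64 ± 0.53 for anti-JAML against isotype (adjusted p = 0.339). For anti-PD-1 against isotype it was 2.15 ± 0.54 (adjusted p = 0.831 in edgeR and 0.0394 in DESeq2).

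**Figure D2:**
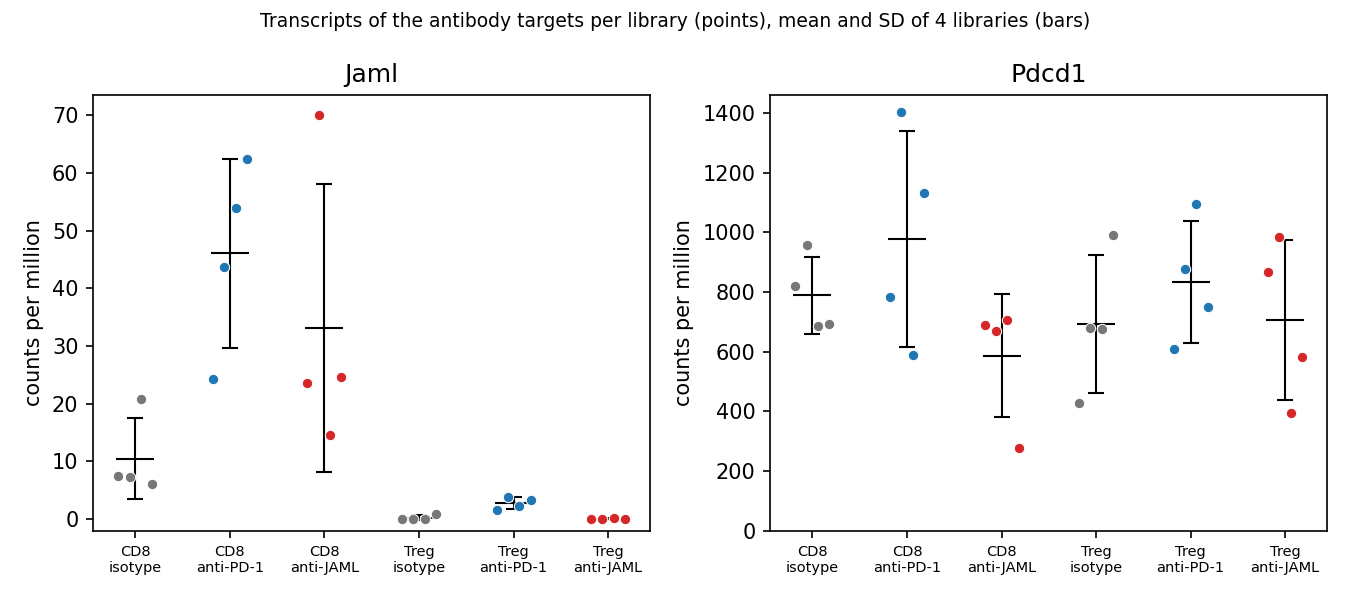
Jaml and Pdcd1 in CPM (y axis) in the 6 groups (x axis), with a point per library and bars for the mean and SD of 4 libraries. Jaml lies between 5.99 and 20.9 CPM in the CD8 isotype libraries, between 24.3 and 62.4 in the CD8 anti-PD-1 libraries, and at most at 3.80 in Treg libraries.

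Anti-JAML was compared with isotype in CD8 T cells to ask which transcripts differ a day after the antibody. Genes of resting and self-renewing T cells were higher as a group. All 15 members of the naive, memory and stem-like list had positive fold changes, with a median log2 value of 1.77 (camera adjusted p = 1.02e-14, p = 0.255 with an estimated correlation). The list score was 6.61 ± 0.73 after anti-JAML and 4.97 ± 0.65 after isotype (unadjusted exact two-sided permutation p = 0.0286, n = 4). Adjusted over the list alone 10 members rose, and over all genes 0 did. Tcf7, which encodes the memory T-cell factor TCF-1, stood at 196 ± 129 against 35.2 ± 20.2 CPM, a log2 fold change of 2.48 ± 0.53 (adjusted p = 0.224). The values were 2.80 ± 0.49 for the transcriptional repressor Klf3 and 1.998 ± 0.50 for S1pr1, a receptor for exit into lymph.

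Trafficking receptors were also higher after anti-JAML in CD8 cells, with a median of 0.77 (adjusted p = 0.000207, p = 0.136 with an estimated correlation). Of these, 5 rose adjusted over the list alone and 0 over all genes, and the integrin chain Itgb1 had 0.99 ± 0.25. Type I interferon response genes had a median of 0.79, with 17 of 21 positive (adjusted p = 0.000779, p = 0.281 with an estimated correlation). Irf7, a regulator of interferon genes, had 0.70 ± 0.20. NF-kB targets had a median of 0.39 (adjusted p = 0.00223, p = 0.291 with an estimated correlation), with the activation marker Cd83 at 1.95 ± 0.47. Melanoma markers had a median of 1.01 over 5 members (adjusted p = 0.0404, p = 0.359 with an estimated correlation).

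Proliferation genes were lower after anti-JAML in CD8 cells, with a median of -0.46 (adjusted p = 1.12e-06, p = 0.255 with an estimated correlation). Of 24 members 8 fell adjusted over the list alone and 0 over all genes, and the survivin gene Birc5 had -0.95 ± 0.23. Glycolysis genes had a median of -0.24 (adjusted p = 0.00223, p = 0.291 with an estimated correlation). Among them 4 fell adjusted over the list alone and 0 over all genes. Oxidative phosphorylation had a median of -0.42 (adjusted p = 1.69e-05, p = 0.291 with an estimated correlation). The unfolded protein response had -0.27 (adjusted p = 0.00476, p = 0.281 with an estimated correlation). Ribosomal proteins had -0.54, with 85 of 96 negative (adjusted p = 8.13e-15, p = 0.374 with an estimated correlation).

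The effector and inhibitory receptor lists each had an adjusted p of 0.0588 here. Of 20 effector genes 6 were positive, but Gzmb (granzyme B) had -0.90 ± 0.34. Prdm1, a transcription factor, had -1.13 ± 0.35. Tissue residency (adjusted p = 0.961) and the early T-cell receptor response (adjusted p = 0.259) did not pass, with Cd69 at 0.67 ± 0.29 and Egr1 at 1.12 ± 0.39. Without single libraries, the melanoma list lost its call without isotype 2 (adjusted p = 0.0921), isotype 4 (0.0855) or anti-JAML 4 (0.153). NF-kB targets lost theirs without anti-JAML 2 (0.0624). Without anti-JAML 2 and 4, which stood apart, melanoma (0.151) and NF-kB (0.172) lost their calls.

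No single gene passed in edgeR, 0 of 12648, with 1483 at an unadjusted p under 0.05 against 632 from chance, while DESeq2 called 210 and voom 1. The smallest adjusted p was that of Gab3, a signalling adaptor, at 57.0 ± 13.7 against 14.8 ± 1.3 CPM (log2 1.94 ± 0.28, adjusted p = 0.0955). Arhgap15, a regulator of Rac, had 0.88 ± 0.16 (adjusted p = 0.134). In the other direction the zinc finger gene Zbtb26 had 1 count against 248. AA474408 was at least 107-fold lower and Derl3, an endoplasmic reticulum protein, at least 56.6-fold lower. All 3 were low in isotype cells, at 4.52 ± 0.50, 5.31 ± 2.86 and 2.80 ± 2.18 CPM.

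Anti-PD-1 was compared with isotype in CD8 T cells to ask what changed after blocking PD-1. Type I interferon response genes had a median log2 fold change of 1.22, with 20 of 21 positive (camera adjusted p = 8.46e-19, p = 0.00955 with an estimated correlation). The list score was 4.82 ± 0.21 against 3.34 ± 0.43 (unadjusted exact two-sided permutation p = 0.0286, n = 4). Of the members 11 rose adjusted over the list alone and 0 over all genes. Irf7 stood at 107 ± 7.4 against 54.4 ± 8.5 CPM, a log2 fold change of 0.97 ± 0.20. Usp18, a brake on interferon signalling, had 1.64 ± 0.36 and Ifit1, which binds viral RNA, 1.42 ± 0.43. Interferon gamma response genes had a median of 0.63 (adjusted p = 9.94e-07, p = 0.0951 with an estimated correlation).

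All 16 glycolysis genes were positive after anti-PD-1 in CD8 cells, with a median of 0.44 (adjusted p = 1.41e-06, p = 0.0951 with an estimated correlation). Ldha, which makes lactate, had 0.45 ± 0.16. The unfolded protein response had a median of 0.22 (adjusted p = 0.000848, p = 0.0951 with an estimated correlation), with the chaperone Hspa5 at 0.81 ± 0.22. The NK list had a median of 0.83 over 4 members (adjusted p = 0.00811, p = 0.0951 with an estimated correlation). Ribosomal proteins were lower, with a median of -0.42 (adjusted p = 7.37e-12, p = 0.523 with an estimated correlation). So were mitochondrially encoded genes, with -0.53 (adjusted p = 0.000195, p = 0.387 with an estimated correlation). Oxidative phosphorylation had -0.20 (adjusted p = 0.0425, p = 0.724 with an estimated correlation). B and plasma cell markers had -1.04 over 3 members (adjusted p = 0.000848, p = 0.0951 with an estimated correlation).

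The effector list did not pass for anti-PD-1 in CD8 cells (adjusted p = 0.376). Prf1, which encodes perforin, stood at 1505 ± 842 against 446 ± 105 CPM (log2 1.75 ± 0.36), Gzmb had 1.01 ± 0.34, and the granzyme gene Gzmk had -0.87 ± 0.24. Adjusted p-values were 0.750 for inhibitory receptors, 0.925 for residency, 0.270 for naive and memory genes, 0.272 for the receptor response, 0.159 for proliferation and 0.0915 for the Treg signature. No single gene passed in edgeR, 0 of 12648, with 710 at an unadjusted p under 0.05 against 632 from chance, 22 in DESeq2 and 3 in voom. The smallest p was that of Nfil3, a leucine zipper transcription factor, at 81.2 ± 9.3 against 37.7 ± 2.7 CPM (log2 1.11 ± 0.21, adjusted p = 0.831).

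With the number of genes detected as a covariate, 6 of the lists for anti-PD-1 in CD8 cells lost their calls. Their adjusted p-values were 0.179 for glycolysis, 0.198 for the unfolded protein response, 0.114 for NK, 0.471 for B and plasma cells, 0.762 for oxidative phosphorylation and 0.893 for mitochondrially encoded genes. Oxidative phosphorylation also lost its call without isotype 2 (0.0606) or 3 (0.0501), anti-PD-1 2 (0.264) or 4 (0.130), or anti-JAML 3 (0.0542) or 4 (0.0692).

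**Figure D3:**
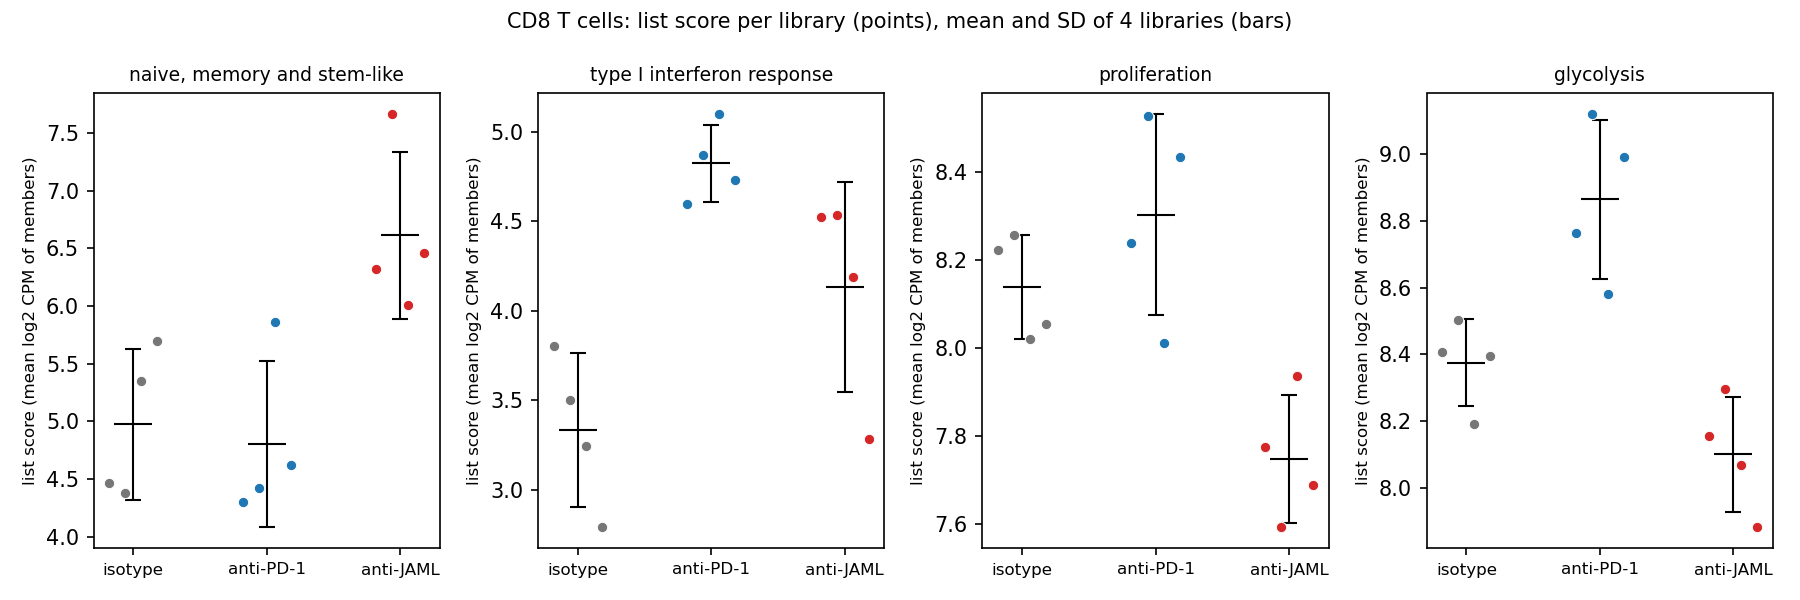
Scores of 4 gene lists in CD8 libraries (y axis, mean log2 CPM of the members) by antibody (x axis), with a point per library and bars for the mean and SD of 4 libraries. Naive, memory and stem-like scores lie between 6.01 and 7.67 after anti-JAML and at most at 5.70 after isotype.

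The antibodies were then compared directly, anti-JAML against anti-PD-1, in CD8 T cells. Nfil3 fell 3.55-fold, from 81.2 ± 9.3 CPM after anti-PD-1 to 22.9 ± 4.5 after anti-JAML (edgeR adjusted p = 0.0105, n = 4), and was the 1 gene called of 12648. With the replicate number as a block it did not pass (adjusted p = 0.0829). Naive, memory and stem-like genes were higher after anti-JAML, with a median log2 of 1.99 and 15 of 15 positive (camera adjusted p = 5.72e-20, p = 0.0427 with an estimated correlation). Adjusted over the list alone 12 rose, and over all genes 0 did. Tcf7 had 2.84 ± 0.54, Klf3 2.41 ± 0.48 and Slamf6, a receptor found on stem-like T cells, 1.99 ± 0.45. Glycolysis genes were lower, with a median of -0.76 (adjusted p = 8.80e-14, p = 0.0308 with an estimated correlation). Of 16 members 12 fell adjusted over the list alone and 0 over all genes, with Ldha at -0.78 ± 0.16 and the enolase gene Eno1 at -0.78 ± 0.17.

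Proliferation genes were lower after anti-JAML than after anti-PD-1 in CD8 cells, with a median of -0.55 (adjusted p = 2.89e-11, p = 0.0427 with an estimated correlation). So was the unfolded protein response, with -0.66 (adjusted p = 1.49e-09, p = 0.0300 with an estimated correlation). Adjusted over the list alone 9 proliferation and 8 unfolded protein genes fell, and over all genes 0. Trafficking receptors were higher, with a median of 0.46 (adjusted p = 0.000942, p = 0.0427 with an estimated correlation) and the chemokine receptor Cxcr3 at 1.24 ± 0.27. B and plasma cell markers had 1.76 over 3 members (adjusted p = 0.000877, p = 0.0427 with an estimated correlation).

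Interferon and effector genes were lower in the same comparison. The type I list had a median of -0.53 (adjusted p = 0.000738, p = 0.195 with an estimated correlation), with Bst2, a factor that tethers virus particles, at -1.06 ± 0.24. The interferon gamma list had -0.26 (adjusted p = 0.0222, p = 0.353 with an estimated correlation). Effector genes had -0.62 (adjusted p = 0.00382, p = 0.353 with an estimated correlation), and 2 of them fell adjusted over the list alone and 0 over all genes. Prf1 had -2.05 ± 0.36 (adjusted p = 0.077) and Gzmb -1.91 ± 0.35 (adjusted p = 0.0838). Oxidative phosphorylation had -0.17 (adjusted p = 0.00971, p = 0.389 with an estimated correlation). Heat shock had -0.35 (adjusted p = 0.0309, p = 0.323 with an estimated correlation), and ribosomal proteins had -0.18 (adjusted p = 0.0222, p = 0.793 with an estimated correlation). Higher lists were NF-kB targets with 0.45 (adjusted p = 0.00396, p = 0.334 with an estimated correlation) and melanoma markers with 1.64 (adjusted p = 0.0222, p = 0.353 with an estimated correlation). Mitochondrially encoded genes had 0.71 (adjusted p = 0.000738, p = 0.353 with an estimated correlation).

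Other genes close to the threshold were Clk1, a kinase of splicing factors (1.15 ± 0.17, adjusted p = 0.0505), Arhgap15 (1.01 ± 0.16, adjusted p = 0.0561) and the tubulin gene Tubb4b (-1.08 ± 0.18, adjusted p = 0.0644). Jaml had -0.50 ± 0.52 (adjusted p = 0.846) and Pdcd1 -0.75 ± 0.31 (adjusted p = 0.418). Inhibitory receptors (adjusted p = 0.0765), the Treg signature (0.124), the receptor response (0.913) and residency (1.00) did not pass. DESeq2 called 262 genes and voom 16. Nfil3 lost its edgeR call without anti-PD-1 2 (adjusted p = 0.0656), anti-PD-1 4 (0.0612) or anti-JAML 1 (0.0566), while 11 genes were called without anti-PD-1 3, Clk1 and Prf1 among them, and 3 without anti-JAML 2. Without anti-JAML 2 and 4, the libraries that stood apart, 0 genes were called and ribosomal proteins turned to higher (1.18e-06). The effector (0.755), NF-kB (0.496), interferon gamma (0.119), oxidative phosphorylation (0.825), melanoma (0.342) and B and plasma (0.273) lists then lost their calls. With genes detected as a covariate 0 genes were called, mitochondrially encoded genes reversed in camera (0.883), and effector (0.134), heat shock (0.140), B and plasma (0.169), interferon gamma (0.222) and melanoma (0.883) lists lost their calls. Calls were also lost without 1 library. This held for oxidative phosphorylation without anti-PD-1 1 (0.0645) or anti-JAML 2 (0.735), for ribosomal proteins without anti-PD-1 1 (0.671), anti-PD-1 3 (0.463) or anti-JAML 2 (0.0991, with the direction reversed), and for interferon gamma without anti-PD-1 2 (0.403) or anti-JAML 4 (0.0604). It held for melanoma without anti-PD-1 2 (0.150) or 4 (0.0699) or anti-JAML 2 (0.0814) or 4 (0.0962), and for heat shock without anti-PD-1 4 (0.0699) or anti-JAML 1 (0.117). Without anti-JAML 2, effector genes reached 0.0948 and NF-kB targets 0.210.

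In Treg cells, anti-JAML against isotype addressed a population with little Jaml transcript. Tissue residency genes were lower as a list, with a median log2 of -0.36 and 9 of 14 negative (camera adjusted p = 0.00182, p = 0.0677 with an estimated correlation). Of these, 2 fell adjusted over the list alone and 0 over all genes. The chemokine receptor Cxcr6 stood at 937 ± 211 against 1648 ± 313 CPM (log2 -0.81 ± 0.20, adjusted p = 0.853, n = 4), and the signalling regulator Rgs1 had -0.61 ± 0.18. Proliferation genes were higher, with a median of 0.33 and 18 of 24 positive (adjusted p = 0.00511, p = 0.710 with an estimated correlation). Glycolysis had a median of 0.34 with 15 of 16 positive (adjusted p = 0.00589, p = 0.710 with an estimated correlation). Ribosomal proteins had -0.18 (adjusted p = 0.00182, p = 0.710 with an estimated correlation), and mitochondrially encoded genes had -0.33 (adjusted p = 0.00816, p = 0.710 with an estimated correlation).

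No single gene passed in edgeR for anti-JAML in Treg cells, 0 of 12981, with 699 at an unadjusted p under 0.05 against 649 from chance, 87 in DESeq2 and 0 in voom. Haus2, a spindle component, stood at 58.6 ± 27.95 against 14.7 ± 3.9 CPM (log2 1.998 ± 0.35, adjusted p = 0.675). Kif2c, a mitotic kinesin, stood at 32.9 ± 13.5 against 7.12 ± 2.15 (log2 2.21 ± 0.40). Bsn, a synaptic scaffold gene, was read at 195 counts against 0, at least 69.2-fold higher. The corepressor gene Rcor1 had -2.004 ± 0.39 and the circadian gene Ciart -1.60 ± 0.35. Spp1, which encodes osteopontin, stood at 4.19 ± 3.49 against 64.8 ± 26.9 CPM (log2 -3.95 ± 0.88). Foxp3, the master regulator of Treg cells, had 0.74 ± 0.34 (adjusted p = 0.904) and Pdcd1 0.03 ± 0.30, and Jaml was read at 4 counts against 12, the latter all in isotype library 4.

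The Treg signature did not pass for anti-JAML (adjusted p = 0.420), with the chemokine receptor Ccr8 at -0.46 ± 0.21. Effector genes had an adjusted p of 0.0736, with the chemokine gene Ccl4 at -1.11 ± 0.44, and inhibitory receptors 0.0808, with Tigit at -0.39 ± 0.15. The receptor response had 0.420 and macrophage markers 0.438. Proliferation lost its call without isotype 2 (0.182), isotype 3, the Treg library that stood apart (0.176), or anti-JAML 1 (0.0515), and glycolysis without isotype 2 (0.207), anti-JAML 1 (0.0515) or anti-JAML 2 (0.0909). Ribosomal proteins lost theirs without isotype 1 (0.317), anti-JAML 1 (0.349) or anti-JAML 2 (0.153), and mitochondrially encoded genes without isotype 1 (0.0605), isotype 3 (0.176) or anti-JAML 1 (0.258). With genes detected as a covariate proliferation and glycolysis had an adjusted p of 0.347 each, and ribosomal proteins (0.000363) and mitochondrially encoded genes (0.0292) turned to higher. Without isotype 4, edgeR called 5 genes. The number of lists past the threshold was 2 without anti-JAML 1, 3 without isotype 1, 2 or 3 and 10 without anti-JAML 3, against 5.

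Anti-PD-1 against isotype in Treg cells gave 3 called genes of 12981 in edgeR, together with higher levels of genes of dividing cells. Nup107, a nuclear pore component, rose 4.02-fold, from 25.2 ± 4.1 to 101.5 ± 24.4 CPM (adjusted p = 0.0151, n = 4). Kif2c rose 8.08-fold, from 7.12 ± 2.15 to 57.6 ± 18.2 CPM (adjusted p = 0.0277). Ypel3, a gene tied to growth arrest, fell 4.20-fold, from 574 ± 111 to 137 ± 40.8 CPM (adjusted p = 0.0151). With the replicate number as a block 0 genes were called (Ypel3 0.106, Nup107 0.251, Kif2c 0.281). All 24 proliferation genes were positive, with a median log2 of 1.14 (camera adjusted p = 1.02e-12, p = 0.149 with an estimated correlation). Adjusted over the list alone 17 rose, and over all genes 0 did. Mki67, a marker of cycling cells, stood at 152 ± 19.3 against 58.3 ± 31.1 CPM (log2 1.39 ± 0.35, adjusted p = 0.121). The list score was 7.96 ± 0.14 against 6.86 ± 0.55 (unadjusted exact two-sided permutation p = 0.0286, n = 4).

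All 16 glycolysis genes were positive after anti-PD-1 in Treg cells, with a median of 0.71 (adjusted p = 1.08e-07, p = 0.201 with an estimated correlation). Of these, 8 rose adjusted over the list alone and 0 over all genes, with the pyruvate kinase gene Pkm at 1.62 ± 0.41 and Eno1 at 0.77 ± 0.17. The unfolded protein response had a median of 0.58 (adjusted p = 0.000601, p = 0.149 with an estimated correlation). Among its members 7 rose adjusted over the list alone and 0 over all genes, with Hspa5 at 1.12 ± 0.27 and the disulphide isomerase gene Pdia4 at 1.32 ± 0.30. Heat shock genes had 0.43 (adjusted p = 0.0252, p = 0.246 with an estimated correlation). Type I interferon genes had 0.44 (adjusted p = 0.00380, p = 0.232 with an estimated correlation). Macrophage markers had a median of 1.36 (adjusted p = 0.0541).

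Residency genes were lower after anti-PD-1 in Treg cells, with a median of -0.55 (adjusted p = 0.000778, p = 0.0883 with an estimated correlation). Of these, 4 fell adjusted over the list alone and 0 over all genes, with Rgs1 at -0.997 ± 0.18 and Rgs2 at -1.22 ± 0.26. Naive and memory genes had -0.73 (adjusted p = 5.26e-05, p = 0.227 with an estimated correlation), with the interleukin-7 receptor Il7r at -1.27 ± 0.29. Trafficking receptors had -0.26 (adjusted p = 0.0252, p = 0.254 with an estimated correlation). The Treg signature had -0.27 (adjusted p = 0.0252, p = 0.149 with an estimated correlation). In it the costimulator Icos had -0.85 ± 0.22 and Ikzf2, which encodes Helios, -0.57 ± 0.19, while the interleukin-2 receptor chain Il2ra had 0.78 ± 0.22. Ribosomal proteins had -0.33 (adjusted p = 4.88e-08, p = 0.563 with an estimated correlation) and mitochondrially encoded genes -0.74 (adjusted p = 5.06e-05, p = 0.345 with an estimated correlation). B and plasma markers had -0.82 over 4 members (adjusted p = 0.0161, p = 0.254 with an estimated correlation).

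Effector genes did not pass for anti-PD-1 in Treg cells (adjusted p = 0.768) and had a median of -0.07 but a mean of 0.47. Gzmb stood at 984 ± 193 against 592 ± 105 CPM (log2 0.73 ± 0.20), and Tbx21, which encodes T-bet, had 1.65 ± 0.41. Inhibitory receptors had an adjusted p of 0.354, with Lag3 at 1.49 ± 0.48 and Tigit at -0.67 ± 0.15, and the receptor response 0.235, with Myc at 0.81 ± 0.18. Below the 3 called genes stood Wdr43, a ribosome assembly factor (1.37 ± 0.21), the lymphotoxin gene Ltb (-1.31 ± 0.21) and Clk1 (-1.13 ± 0.19), each with an adjusted p of 0.0705. Jaml had 162 counts against 12 (log2 3.74 ± 2.05, adjusted p = 0.464) and Pdcd1 0.30 ± 0.30 (adjusted p = 0.769). At an unadjusted p under 0.05 there were 1835 genes against 649 from chance. DESeq2 called 623 genes and voom 60, and voom gave Kif2c an adjusted p of 0.0745.

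The gene calls in this comparison rested on single libraries. In edgeR 0 genes were called without isotype 3, anti-PD-1 2 or anti-PD-1 3, 1 without anti-PD-1 4, 5 without anti-JAML 1 or 4, 23 without anti-PD-1 1 and 122 without isotype 4. With genes detected as a covariate 0 genes were called, ribosomal proteins (0.0569) and mitochondrially encoded genes (0.418) reversed, and the Treg signature (0.0660) and B and plasma markers (0.874) lost their calls. Without anti-PD-1 1 and 4, the libraries highest in Lyz2, 12 genes were called, and the Treg signature, heat shock, B and plasma markers (each 0.129) and trafficking (0.586) lost their calls. Ypel3 reached an adjusted p of 0.114 without anti-PD-1 2 or 3 and 0.0805 without isotype 3. Nup107 reached 0.114 without anti-PD-1 2 or 3, 0.109 without isotype 3, 0.0713 without anti-PD-1 4 and 0.0573 without isotype 1. Kif2c reached between 0.0573 and 0.161 without isotype 1, 2 or 3, anti-PD-1 2, 3 or 4, or anti-JAML 3. Without 1 library, 4 of the 12 lists lost their calls. The Treg signature did so without isotype 2 (0.0805), isotype 4 (0.0513) or anti-PD-1 1 (0.123), and trafficking without isotype 2 (0.0829), anti-PD-1 1 (0.163) or anti-PD-1 4 (0.0565). Heat shock lost its call without isotype 2 (0.113), isotype 4 (0.170) or anti-PD-1 4 (0.0513), and B and plasma markers without isotype 3, which stood apart (0.0692).

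**Figure D4:**
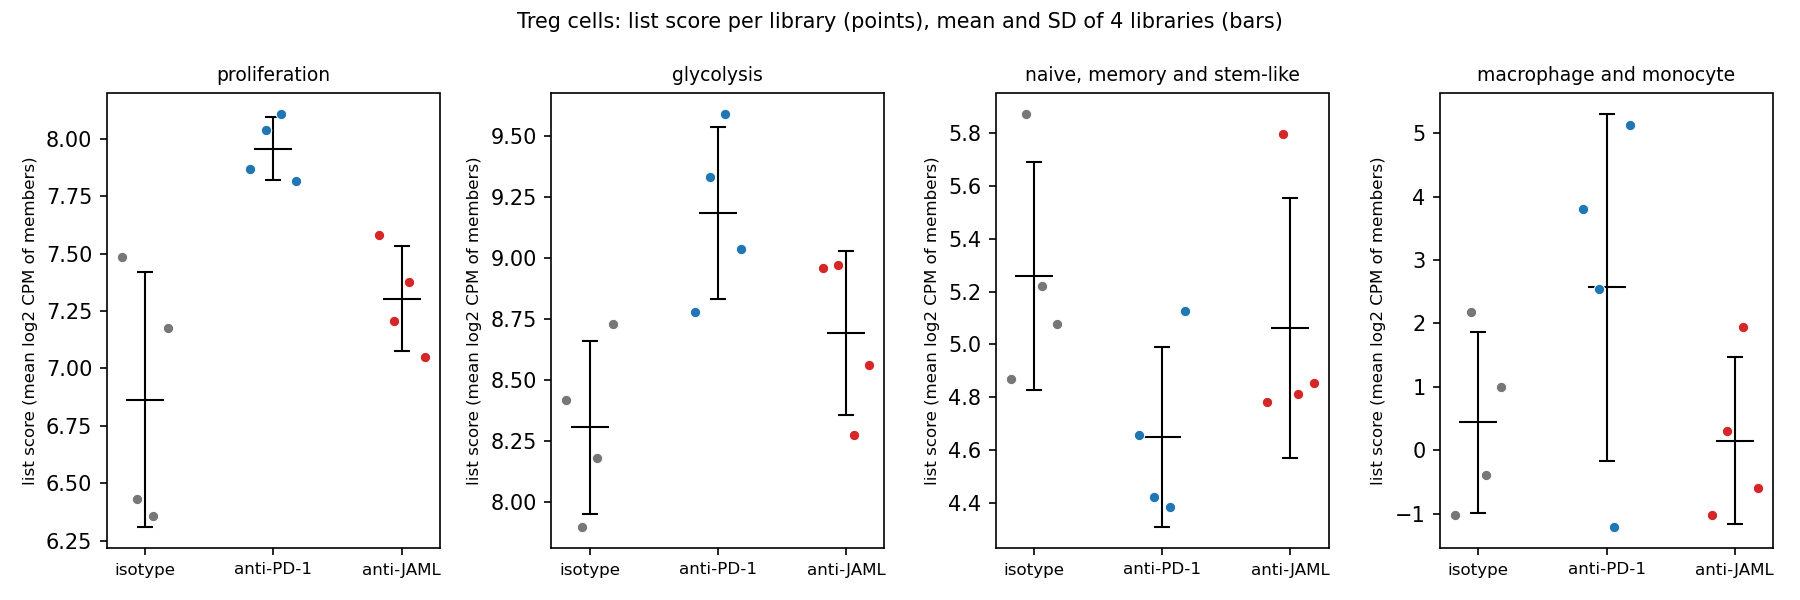
Scores of 4 gene lists in Treg libraries (y axis, mean log2 CPM of the members) by antibody (x axis), with a point per library and bars for the mean and SD of 4 libraries. Proliferation scores lie between 7.81 and 8.11 after anti-PD-1, between 7.05 and 7.58 after anti-JAML and between 6.36 and 7.48 after isotype.

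Anti-JAML was set directly against anti-PD-1 in Treg cells as well. All 24 proliferation genes were negative, with a median log2 of -0.70 (camera adjusted p = 1.64e-10, p = 0.168 with an estimated correlation). Scores were 7.30 ± 0.23 against 7.96 ± 0.14 (unadjusted exact two-sided permutation p = 0.0286, n = 4). Adjusted over the list alone 0 passed, with the topoisomerase gene Top2a at -0.98 ± 0.28 and Mki67 at -0.94 ± 0.35. Type I interferon genes had a median of -0.61, with 19 of 21 negative (adjusted p = 2.17e-06, p = 0.115 with an estimated correlation). Bst2 stood at 57.3 ± 13.3 against 181 ± 56.3 CPM (log2 -1.66 ± 0.24, adjusted p = 0.122). The unfolded protein response had -0.49 (adjusted p = 6.89e-05, p = 0.115 with an estimated correlation). The naive and memory list was higher after anti-JAML, with a median of 0.39 (adjusted p = 0.000112, p = 0.185 with an estimated correlation) and Il7r at 1.22 ± 0.29.

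Macrophage and monocyte markers were lower after anti-JAML too. The median was -2.61, with 13 of 13 negative (adjusted p = 0.000101, p = 0.249 with an estimated correlation). The Fc receptor chain gene Fcer1g stood at 11.7 ± 14.8 against 71.7 ± 69.8 CPM. Interferon gamma genes had -0.33 (adjusted p = 6.89e-05, p = 0.168 with an estimated correlation), and glycolysis had -0.37 (adjusted p = 6.89e-05, p = 0.226 with an estimated correlation). Heat shock had -0.45 (adjusted p = 0.00498, p = 0.168 with an estimated correlation), and the receptor response had -0.35 (adjusted p = 0.00396, p = 0.168 with an estimated correlation). Effector genes had -0.40 (adjusted p = 0.00481, p = 0.168 with an estimated correlation), and 4 fell adjusted over the list alone and 0 over all genes.

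Higher after anti-JAML than after anti-PD-1 in Treg cells were trafficking receptors, with a median of 0.02 (adjusted p = 0.0466, p = 0.251 with an estimated correlation). B and plasma markers had 0.89 (adjusted p = 0.00949, p = 0.226 with an estimated correlation). Ribosomal proteins had 0.19 (adjusted p = 0.000122, p = 0.612 with an estimated correlation), and mitochondrially encoded genes 0.36 (adjusted p = 0.00890, p = 0.508 with an estimated correlation). The Treg signature did not pass (adjusted p = 0.0546), with Ikzf2 at 0.75 ± 0.19. Residency (adjusted p = 0.368) and inhibitory receptors (adjusted p = 0.566) did not pass either, with Lag3 at -1.57 ± 0.48. Single genes did not pass in edgeR, 0 of 12981, with 742 at an unadjusted p under 0.05 against 649 from chance, 70 in DESeq2 and 0 in voom. Ypel3 (1.57 ± 0.24) and Spp1 had an adjusted p of 0.122, and Spp1 stood at 4.19 ± 3.49 against 294 ± 183 CPM and passed without anti-JAML 4 (0.0459). Pdcd1 had -0.28 ± 0.30, and Jaml was read at 4 counts against 162.

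Without the pair of Treg libraries highest in Lyz2, 6 lists lost their calls in this comparison. Adjusted p-values were then 0.689 for macrophages and for trafficking, 0.283 for B and plasma, 0.211 for effector, 0.0944 for the receptor response and 0.0829 for heat shock. B and plasma markers and ribosomal proteins (0.0532 each) and mitochondrially encoded genes (0.0734) lost theirs with genes detected as a covariate. Trafficking was also lost without anti-JAML 1 (0.329), anti-PD-1 1 (0.292), anti-JAML 2 (0.142), anti-PD-1 4 (0.110) or isotype 1 (0.050003). Ribosomal proteins were lost without anti-PD-1 3 (0.379) or anti-JAML 3 (0.0682), and effector genes without anti-JAML 1 (0.0820) or anti-PD-1 1 (0.0611). B and plasma markers were lost without anti-JAML 2 (0.0760) or 4 (0.0722), and mitochondrially encoded genes without anti-PD-1 3 (0.0792) or 4 (0.0701) or anti-JAML 3 (0.0646) or 4 (0.0722).

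CD8 and Treg cells were compared under isotype antibody to check the sort and to describe their baseline difference. Cd8a (mm10 chromosome 6, 71373427 to 71379173) stood at 1649 ± 161 CPM in CD8 cells and 0 in Treg cells, at least 41355-fold higher (edgeR adjusted p = 6.51e-06, n = 4). Cd8b1 (chromosome 6, 71322788 to 71337494) stood at 1019 ± 78.8 against 31.8 ± 17.9 CPM (adjusted p = 0.000213). Cd4 (chromosome 6, 124864692 to 124888221) was 0 against 269 ± 55.8 CPM, at least 4951-fold lower (adjusted p = 4.28e-05). Foxp3 (chromosome X, 7573644 to 7595245) was 0 against 68.8 ± 18.8 CPM, at least 1268-fold lower (adjusted p = 0.000139). In all, 1791 of 11680 genes differed, 959 higher and 832 lower in CD8 cells. Jaml had 575 counts in CD8 and 12 in Treg cells, a log2 fold change of 5.76 ± 1.78 (adjusted p = 0.0593, with 0.0451 in voom and 0.000832 in DESeq2), and passed without Treg isotype 4 (0.00864). Pdcd1 stood at 783 ± 137 against 646 ± 196 CPM and did not pass (adjusted p = 0.495).

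The CD8 lineage list was higher in CD8 cells, with a median log2 of 4.90 (camera adjusted p = 1.07e-39, p = 0.000409 with an estimated correlation). Of 13 members 10 rose over all genes and 10 adjusted over the list alone. The NK receptor gene Klrd1 was at least 9404-fold higher and Eomes, a T-box factor of killer cells, at least 895-fold higher. Effector genes had a median of 1.62 (adjusted p = 8.04e-06, p = 0.0395 with an estimated correlation). Over all genes 12 of them were higher and 2 lower, and adjusted over the list alone 14 and 3. Prf1 had 3.90 ± 0.43 and the interferon gamma gene Ifng 3.05 ± 0.34, but the receptor gene Klrg1 -4.26 ± 0.39.

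Proliferation genes were also higher in CD8 cells, with a median of 1.15 (adjusted p = 2.14e-13, p = 0.137 with an estimated correlation) and 18 of 24 called over all genes and 20 adjusted over the list alone. Ribosomal proteins had 0.73, with 54 of 92 called and 67 adjusted over the list alone (adjusted p = 8.38e-19, p = 0.247 with an estimated correlation). Oxidative phosphorylation had 0.63, with 10 of 20 called and 19 adjusted over the list alone (adjusted p = 3.29e-07, p = 0.151 with an estimated correlation). The unfolded protein response had 0.70 (adjusted p = 0.00749, p = 0.290 with an estimated correlation), and heat shock had 0.36 (adjusted p = 0.00890, p = 0.290 with an estimated correlation). The NK list passed with 2 of 3 members called (adjusted p = 0.00429, p = 0.0995 with an estimated correlation). Of the genes with the smallest p, the serpin gene Serpine2 was at least 5077-fold higher. Themis, a T-cell signalling gene, had 1.86 ± 0.15 and Nup107 2.03 ± 0.19.

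The Treg signature was lower in CD8 than in Treg cells, with a median of -3.46 (adjusted p = 1.03e-47, p = 0.000257 with an estimated correlation). Of 18 members 16 fell over all genes and 17 adjusted over the list alone. Tnfrsf4, which encodes OX40, stood at 511 ± 26.3 against 2588 ± 342 CPM, Icos had -3.42 ± 0.22 and the inhibitory receptor Ctla4 -2.62 ± 0.22. Type I interferon genes were lower, with a median of -1.71 (adjusted p = 7.48e-15, p = 0.00495 with an estimated correlation) and 12 of 21 called over all genes and 14 adjusted over the list alone. Interferon gamma genes had -1.37 (adjusted p = 5.75e-15, p = 0.00126 with an estimated correlation), with 13 called over all genes and 17 adjusted over the list alone.

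Trafficking receptors had a median of -1.54 (adjusted p = 1.91e-13, p = 0.00382 with an estimated correlation). Residency genes had -1.87 (adjusted p = 1.58e-08, p = 0.00533 with an estimated correlation), and the receptor response had -1.07 (adjusted p = 1.03e-06, p = 0.00533 with an estimated correlation). The CD4 lineage list had -2.34 (adjusted p = 1.88e-15, p = 0.00470 with an estimated correlation). NF-kB targets had -1.31 (adjusted p = 7.78e-08, p = 0.0696 with an estimated correlation). Of the genes with the smallest p, the calcitonin receptor partner Ramp1 had -3.87 ± 0.23, the nuclear receptor Rora -2.96 ± 0.19 and the lysosomal gene Gm2a -2.12 ± 0.14.

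Inhibitory receptors did not pass in camera between the populations (adjusted p = 0.510), but their score was higher in CD8 cells by permutation (adjusted p = 0.0464). Nor did the naive and memory list pass (adjusted p = 0.161), whose median was 0.01 and mean -0.32. Adjusted p-values were 0.455 for glycolysis, 0.0888 for B and plasma cells and 0.592 for mitochondrially encoded genes. The number of genes called was 1117 without CD8 isotype 2, 1147 without CD8 isotype 1 and 1093 with genes detected as a covariate, against 1791.

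An interaction, CD8 minus Treg, tested whether the anti-JAML effect differed between the populations. The naive, memory and stem-like list responded more in CD8 cells, by 1.80 in list score (camera adjusted p = 1.06e-15, p = 0.0417 with an estimated correlation). Tcf7 means after isotype and anti-JAML were 35.3 and 199 CPM in CD8 cells and 33.2 and 21.5 CPM in Treg cells (interaction log2 3.07 ± 0.76, adjusted p = 0.368). Trafficking receptors differed by 0.48 (adjusted p = 0.000280, p = 0.0398 with an estimated correlation). Proliferation differed by -0.87 (adjusted p = 9.74e-11, p = 0.0905 with an estimated correlation). Glycolysis differed by -0.70 (adjusted p = 2.50e-07, p = 0.0905 with an estimated correlation). The unfolded protein response differed by -0.43 (adjusted p = 0.00255, p = 0.104 with an estimated correlation), and oxidative phosphorylation by -0.40 (adjusted p = 0.0117, p = 0.486 with an estimated correlation). Type I interferon genes differed by 0.61 (adjusted p = 7.47e-05, p = 0.0905 with an estimated correlation), and interferon gamma genes by 0.45 (adjusted p = 0.00441, p = 0.265 with an estimated correlation). Ribosomal proteins differed by -0.60 (adjusted p = 1.80e-05, p = 0.537 with an estimated correlation), and mitochondrially encoded genes by 0.46 (adjusted p = 0.0286, p = 0.496 with an estimated correlation).

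No single gene passed the anti-JAML interaction in edgeR, 0 of 14591, with 1224 at an unadjusted p under 0.05, 283 in DESeq2 and 0 in voom. Gab3 (2.35 ± 0.45) and Kif2c (-2.47 ± 0.48) had an adjusted p of 0.109, and Slfn1, a growth regulator of T cells, had 1.57 ± 0.31 (adjusted p = 0.111). The tubulin ligase gene Ttl stood at 0 CPM in Treg cells after isotype and 5.72 ± 4.43 after anti-JAML (adjusted p = 0.0961). Jaml had 3.19 ± 1.52 (adjusted p = 0.587), a value set by few Treg counts that was -1.39 without Treg isotype 4, and Pdcd1 -0.51 ± 0.44 (adjusted p = 0.891). Lists that did not pass had adjusted p-values of 0.0690 for residency and the receptor response and 0.0743 for macrophages.

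In edgeR 19 genes passed the anti-JAML interaction without Treg isotype 4, among them Slfn1 (adjusted p = 0.0149), Ttl (0.0324) and Gab3 (0.0489). Without Treg isotype 2 or Treg anti-JAML 2, 2 genes passed, and without Treg isotype 1 or Treg anti-JAML 1, 1 did. The mitochondrial list lost its call without Treg isotype 1 (0.0779) or 3 (0.151), Treg anti-JAML 1 (0.266), CD8 isotype 2 (0.0843), or CD8 anti-JAML 1 (0.0668) or 4 (0.368). Oxidative phosphorylation lost its call without Treg isotype 4 (0.0858), Treg anti-JAML 3 (0.120) or CD8 anti-JAML 2 (0.436), and ribosomal proteins without CD8 anti-JAML 2 (0.268). The mitochondrial list reversed with genes detected as a covariate (0.0957). Without the libraries that stood apart (CD8 anti-JAML 2 and 4 and Treg isotype 3) oxidative phosphorylation (0.624) and mitochondrial genes (0.136) lost their calls and ribosomal proteins reversed (0.780).

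For anti-PD-1 the interaction gave a difference of -0.95 in the proliferation list (camera adjusted p = 4.48e-14, p = 0.0466 with an estimated correlation). Kif2c went from 7.13 ± 2.07 to 56.6 ± 18.3 CPM in Treg cells and from 43.8 ± 6.8 to 53.7 ± 20.3 CPM in CD8 cells (log2 -2.74 ± 0.48, adjusted p = 0.0764). Nup107 had -1.52 ± 0.29 and Mki67 -1.46 ± 0.42. Type I interferon genes differed by 0.60 (adjusted p = 6.59e-06) and residency genes by 0.51 (0.0133). The naive and memory list differed by 0.41 (adjusted p = 0.0122) and interferon gamma genes by 0.33 (0.0133). With an estimated correlation p was 0.0466, 0.0466, 0.544 and 0.363 in that order. The NK list differed by -1.28 (adjusted p = 0.0444), and the CD8 lineage by -1.10 and trafficking by 0.22 (each 0.0496). Each had p = 0.187 with an estimated correlation. In Treg cells low scores rose, from -2.30 to -0.28 for NK and 2.64 to 3.62 for the CD8 lineage. In CD8 cells they went from 3.08 to 3.81 and from 8.55 to 8.44.

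No single gene passed the anti-PD-1 interaction in edgeR, 0 of 14591, with 912 at an unadjusted p under 0.05, 201 in DESeq2 and 0 in voom. Ttl had an adjusted p of 0.0764. Jaml had -1.72 ± 1.30 and Pdcd1 -0.03 ± 0.44. Without Treg isotype 4, 12 genes passed, with 5 without Treg isotype 1, 3 without Treg anti-JAML 2, 2 without Treg anti-PD-1 1 and 1 without Treg isotype 2 or CD8 anti-JAML 3. Kif2c had an adjusted p between 0.0117 and 0.0407 without Treg isotype 1 or 4, Treg anti-PD-1 1 or Treg anti-JAML 2. Without Treg isotype 2, 3 lists passed against 8, and 5 without CD8 isotype 1, CD8 anti-PD-1 2 or CD8 anti-JAML 4. Without Treg isotype 2 naive and memory, CD8 lineage, trafficking and NK had an adjusted p of 0.141 each and interferon gamma 0.0541. Without the pair of Treg libraries highest in Lyz2, CD8 lineage (0.550), trafficking (0.455) and NK (0.436) were lost, without the libraries that stood apart trafficking (0.0602), and with the replicate number as a block CD8 lineage (0.0788) and NK (0.0954). CD8 lineage (0.323), NK (0.240) and trafficking (0.189) were lost without Treg anti-PD-1 1, and interferon gamma (0.314), trafficking (0.144) and NK (0.0632) without CD8 anti-PD-1 2. Without CD8 anti-PD-1 3 the naive and memory list reached 0.369 and trafficking 0.0984, and without CD8 isotype 1 or 2 the naive and memory list reached 0.0592 and 0.0536. Interferon gamma reached 0.0546 without Treg anti-PD-1 3. The NK list reached between 0.0521 and 0.0978 without Treg isotype 1, Treg anti-PD-1 2, CD8 isotype 3, CD8 anti-PD-1 1 or CD8 anti-JAML 4. The CD8 lineage reached between 0.0505 and 0.0970 without Treg anti-JAML 3, CD8 isotype 1 or 2, CD8 anti-PD-1 1, 2 or 4, or CD8 anti-JAML 2, 3 or 4. Trafficking reached between 0.0505 and 0.110 without Treg isotype 3, Treg anti-PD-1 4, Treg anti-JAML 2, 3 or 4, CD8 isotype 1 or 3, or CD8 anti-JAML 3 or 4.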

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

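Of the tests in this part, those on libraries that stood apart, on RNA of CD4 T cells or B cells and on RNA of macrophages were chosen after the results were seen. Genes detected was chosen as a covariate after the data were seen, but the bounds for it were set before its own result was known.

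The naive, memory and stem-like list was higher in CD8 cells after anti-JAML, with scores of 6.32, 7.67, 6.01 and 6.46 against 4.38 to 5.70 after isotype. With an estimated correlation it did not pass (p = 0.255). With genes detected as a covariate the list's median log2 fold change was 1.72, close to 1.77 without it, which argues against the number of genes detected. Without the pair that stood apart, libraries 1 and 3 lay 0.31 above isotype, as the scores already show. The highest Cd4 or Cd79a level in any CD8 library was 0.877 CPM, too low for RNA of naive CD4 T cells or B cells to carry the list. An effect of the antibody on the makeup or state of the CD8 cells may be the source, as a hypothesis, and a difference between mice or tumours in how many little-stimulated CD8 cells were sorted stays open and was not tested.

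Type I interferon genes were higher in CD8 cells after anti-PD-1, with scores between 4.60 and 5.10 against 2.79 to 3.81 after isotype (p = 0.00955 with an estimated correlation). The median was 0.93 with genes detected as a covariate and 1.22 without it, so that the number of genes detected was not the whole source. All anti-PD-1 scores lay above isotype, so those low in Lyz2 had to (by 0.79), which decides nothing on macrophage RNA. A response to the antibody may be the source, as a hypothesis, and macrophage RNA and unlabelled differences between mice stay open.

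Proliferation genes were higher in Treg cells after anti-PD-1, with scores between 7.81 and 8.11 against 6.36 to 7.48 after isotype. With an estimated correlation the list did not pass (p = 0.149). Without anti-PD-1 libraries 1 and 4, highest in Lyz2, the median log2 fold change was 1.29 (1.14 with them). That argues against macrophage RNA as the whole source, but of libraries 2 and 3 only 3 was low (115 and 2.07 CPM). All lay above isotype, 2 and 3 by at least 0.55. With genes detected as a covariate the median fell to 0.58 and the list passed at the preset correlation (adjusted p = 4.01e-09). The number of genes detected differs between these groups, and cycling cells hold more RNA, so that library quality and cell division cannot be told apart here. Both remain candidate explanations.

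Other splits of the same libraries were counted for each comparison. For CD8 cells with anti-JAML against isotype, 35 of 35 splits gave at least the 0 genes called (highest other 0) and 5 gave at least the 10 lists (highest other 12). For CD8 cells with anti-PD-1 against isotype the numbers were 35 for 0 genes (highest other 0) and 8 for 9 lists (highest other 11). For CD8 cells with anti-JAML against anti-PD-1 they were 2 for 1 gene (highest other 5) and 2 for 15 lists (highest other 16). For Treg cells with anti-JAML against isotype they were 35 for 0 genes (highest other 1) and 15 for 5 lists (highest other 9). For Treg cells with anti-PD-1 against isotype they were 2 for 3 genes (highest other 124) and 3 for 12 lists (highest other 14). For Treg cells with anti-JAML against anti-PD-1 they were 35 for 0 genes (highest other 0) and 1 for 14 lists (highest other 10). For CD8 against Treg cells they were 1 for 1791 genes (highest other 0) and 7 for 16 lists (highest other 20). Of 100 splits drawn for each interaction, 100 gave at least the 0 genes for anti-JAML (highest other 15) and 100 for anti-PD-1 (highest other 137), and 5 gave at least the 10 lists for anti-JAML (highest other 11) and 20 the 8 lists for anti-PD-1 (highest other 13). Where 0 genes were called every split reaches that number, so that these splits decide nothing there. Of the other counts, only the real split reached its number for the genes of CD8 against Treg cells. The same held for the lists of anti-JAML against anti-PD-1 in Treg cells. Each is 1 split of 35, the smallest share possible and not adjusted over the counts, so that it alone does not exclude chance. Those lists are camera's count at the preset correlation, and 0 of them passed with an estimated correlation or by adjusted permutation. The 6 other splits with at least 16 lists for CD8 against Treg cells kept 3 of 4 libraries of each population together, so that this count says little of chance, and 14 of the 16 lists passed by adjusted permutation. The CD8 split with 5 genes set libraries 1 and 3 of both antibodies, with 8.39% to 8.65% of counts in ribosomal protein genes, against 2 and 4 of both, with 4.09% to 6.22%. It points to a structure other than the antibody. CD8 isotype 2 and 4 had 8.50% and 9.16%, so that share need not follow the replicate number. The split with 124 genes set Treg isotype 1, 2 and 3 and anti-PD-1 1, with 12643 to 14031 genes detected, against isotype 4 and anti-PD-1 2, 3 and 4, with 14378 to 15162. It parts the libraries by the number of genes detected, and it also keeps 6 of 8 on the side of their antibody, exchanging isotype 4 and anti-PD-1 1, without which, 1 at a time, 122 and 23 genes were called. It points to a structure of the samples, and whether that is genes detected or an antibody effect with a pair of odd libraries stays open. The split with 137 points to a structure too, and what it follows was not tested.

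Lists whose antibody effect differed between CD8 and Treg cells in camera at the preset correlation are given as differences of list score. With an estimated correlation 2 of 10 passed for anti-JAML and 3 of 8 for anti-PD-1, and by adjusted permutation 0. For anti-JAML they were 1.80 for naive, memory and stem-like genes, -0.87 for proliferation, 0.61 for type I interferon, 0.45 for interferon gamma, 0.48 for trafficking, -0.70 for glycolysis, -0.40 for oxidative phosphorylation, -0.43 for the unfolded protein response, -0.60 for ribosomal proteins and 0.46 for mitochondrially encoded genes. For anti-PD-1 they were 0.51 for residency, 0.41 for naive, memory and stem-like genes, -0.95 for proliferation, 0.60 for type I interferon, 0.33 for interferon gamma, -1.10 for the CD8 lineage, 0.22 for trafficking and -1.28 for NK genes.

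A single library was flagged in 4 of 66 library measures, 11 of 159 list scores and 22 of 482 named genes. The gap to the other 3 was large for the group's range, but some were small. Chance marks about 1 group in 20. Treg anti-PD-1 library 1 was flagged most, 7 times. It had 3.38% of counts in mitochondrial genes, a TMM factor of 0.961 and a first component of -41.8. Scores were 5.84 for residency, 6.49 for NF-kB and 8.67 for oxidative phosphorylation, and Eomes had 1.20 CPM. CD8 isotype library 3 had scores of 4.23 for dendritic and 5.13 for erythroid genes, and 40.5 CPM of Eomes, 3501 of Rpl4 and 81.8 of Slfn1. In isotype Treg cells library 4 had a TMM factor of 1.04, a CD4 lineage score of 3.95, 18.2 CPM of Rcor1 and 1977 of Rps27. Library 1 had an oxidative phosphorylation score of 8.57, 33.3 CPM of Ciart, 129 of Irf7 and 2314 of Rpl4. Library 2 had 269.8 CPM of Il7r. In anti-PD-1 CD8 cells library 1 had an erythroid score of 0.63 and 283 CPM of Cd82, library 2 an interferon gamma score of 7.22, and library 4 had 107 CPM of Arhgap15 and 113 of Gzmk. In anti-JAML CD8 cells library 2 had 195 CPM of Ccnb2, and library 4 a MAPK score of 4.10 and 277 CPM of Pdcd1. CD8 isotype library 2 had 345 CPM of Ctsw and library 4 had 185 of Gm2a. In Treg cells, anti-PD-1 library 2 had 44.3 CPM of Il7r and library 4 had 197 of Ypel3. Anti-JAML library 1 had 314 CPM of Ccnb1 and 1000.7 of mt-Nd5, library 2 a naive and memory score of 5.80, and library 4 had 99.9 CPM of Myc.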

How the results depend on the processing

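Leaving out the libraries that stood apart, leaving out the pair of Treg libraries highest in Lyz2, the covariate and the count of lists by permutation were tests chosen after the data were seen. Where a cause is not named, the cause was not tested. Among named genes the direction and side of the threshold were the same in 293 fits with RLE normalization (3 newly past the threshold, 1 reversed), 289 with no filter (7 and 1), 163 with DESeq2 (131 and 1) and 271 with voom (25, with 1 lost). They were the same in 287 with genes detected as a covariate (4 lost, 6 reversed), 292 without the libraries that stood apart (4 lost, 1 reversed) and 89 without the pair highest in Lyz2 (4 newly past). Of the lists past the threshold, 21 kept their call with an estimated correlation and 78 lost it, and 46 kept it in fry and 53 lost it. With RLE in place of TMM the median of all genes moved by less than 0.1 in each comparison, and the calls for CD8 against Treg cells went from 959 higher and 832 lower to 905 and 881. No library lay below 25% of the median total, so leaving out shallow libraries gave no value of its own. Depth limits low genes such as Jaml in Treg cells.

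Genes called by DESeq2 numbered 210, 22 and 262 in CD8 cells (anti-JAML against isotype, anti-PD-1 against isotype, anti-JAML against anti-PD-1, with 0, 0 and 1 in edgeR). They numbered 87, 623 and 70 in Treg cells in the same order (0, 3 and 0 in edgeR), and 283 and 201 for the interactions of anti-JAML and anti-PD-1 (0 and 0). With voom they were 1, 3 and 16 in CD8 cells and 60 for anti-PD-1 against isotype in Treg cells. For anti-JAML against anti-PD-1 in CD8 cells there were 4 with RLE normalization, 9 with no filter, and 0 with the compared groups alone, without the libraries that stood apart or with genes detected as a covariate. For anti-PD-1 against isotype in Treg cells there were 0 with the compared groups alone, without the libraries that stood apart or with the covariate, and 12 without the pair highest in Lyz2. The covariate gave 1093 for CD8 against Treg cells, against 1791. The interactions had 1 (anti-JAML) and 4 (anti-PD-1) genes with the compared groups alone, and 2 for anti-PD-1 without the pair highest in Lyz2.

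Lists with an adjusted p under 0.05 with an estimated correlation and by fry, and with an unadjusted p under 0.05 by permutation, were 0, 3 and 4 for anti-JAML in CD8 cells (10 in camera), 6, 7 and 7 for anti-JAML against anti-PD-1 in CD8 cells (15), 0, 1 and 0 for anti-JAML in Treg cells (5), 0, 6 and 6 for anti-PD-1 in Treg cells (12) and 0, 2 and 3 for anti-JAML against anti-PD-1 in Treg cells (14). They were 2, 5 and 4 for the anti-JAML interaction (10) and 3, 0 and 2 for the anti-PD-1 interaction (8). For anti-PD-1 in CD8 cells (9) they were 1 with an estimated correlation, 4 by permutation and 3 with the covariate, and for CD8 against Treg cells (16) 9 with an estimated correlation. With the permutation p adjusted over the lists, 0 passed in each antibody comparison and interaction and 16 for CD8 against Treg cells, of which 14 passed in camera. Without the libraries that stood apart there were 9 for anti-JAML against anti-PD-1 in CD8 cells, as with the covariate, and 3 for anti-JAML in Treg cells. Without the pair highest in Lyz2 there were 8 for anti-JAML against anti-PD-1 in Treg cells.

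Directions reversed in few results. With genes detected as a covariate, mitochondrially encoded genes reversed for anti-JAML against anti-PD-1 (adjusted p = 0.883) and anti-PD-1 against isotype (0.893) in CD8 cells, for anti-JAML (0.0292) and anti-PD-1 (0.418) against isotype in Treg cells, and for the anti-JAML interaction (0.0957). Ribosomal proteins reversed for anti-JAML (0.000363) and anti-PD-1 (0.0569) in Treg cells. They also reversed without the libraries that stood apart, for anti-JAML against anti-PD-1 in CD8 cells (1.18e-06) and the anti-JAML interaction (0.780). With the covariate Pdcd1 had log2 values of -0.43 for anti-PD-1 in CD8 cells, -0.36 for anti-JAML and -0.20 for anti-PD-1 in Treg cells and 0.28 for the anti-PD-1 interaction, and for anti-JAML in Treg cells Tnfrsf18 had 0.0028 and mt-Co1 0.38. Pdcd1 in the anti-PD-1 interaction had 0.0126 with DESeq2 and with RLE, 0.0418 with no filter and 0.0284 without the libraries that stood apart.

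Without 1 library at a time, the genes called in CD8 cells stayed at 0 for either antibody against isotype and lay between 0 (without anti-PD-1 2 or 4 or anti-JAML 1) and 11 (without anti-PD-1 3) for anti-JAML against anti-PD-1, with 3 without anti-JAML 2. In Treg cells they lay between 0 and 5 for anti-JAML (5 without isotype 4). For anti-PD-1 they lay between 0 (without isotype 3 or anti-PD-1 2 or 3) and 122 (without isotype 4), with 23 without anti-PD-1 1, 5 without anti-JAML 1 or 4 and 1 without anti-PD-1 4. For anti-JAML against anti-PD-1 they lay between 0 and 1 (without anti-JAML 4). For CD8 against Treg cells they lay between 1117 (without CD8 isotype 2, with 1147 without CD8 isotype 1) and 2125 (without Treg isotype 1). For the interactions they lay between 0 and 19 for anti-JAML and between 0 and 12 for anti-PD-1, both highest without Treg isotype 4. Lists lay between 9 and 15 for anti-JAML, 8 and 13 for anti-PD-1 and 10 and 16 for the direct comparison in CD8 cells. In Treg cells they lay between 2 (without anti-JAML 1) and 10 (without anti-JAML 3), between 10 and 14, and between 12 and 14. They lay between 16 and 17 for CD8 against Treg cells, between 9 and 13 for the anti-JAML interaction and between 3 (without Treg isotype 2) and 11 (without Treg isotype 1) for the anti-PD-1 interaction. Ribosomal proteins for anti-JAML against anti-PD-1 in CD8 cells had an adjusted p between 1.13e-06 (without anti-PD-1 2) and 0.671 (without anti-PD-1 1), and reversed without anti-JAML 2 (0.0991). For anti-JAML in Treg cells Jaml lay between -4.77 (without anti-JAML 3) and 3.03 (without isotype 4), and Pdcd1 between -0.17 (without anti-JAML 2) and 0.25 (without isotype 4), also negative without isotype 1 or anti-JAML 1. Jaml in the anti-JAML interaction lay between -1.39 (without Treg isotype 4) and 6.17 (without Treg anti-JAML 3), where it has few Treg counts, and Pdcd1 in the anti-PD-1 interaction between -0.24 and 0.18.

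Groups share replicate numbers, which the labels do not explain. Deviations of libraries with 1 number in different groups correlated between -0.176 and 0.149 within a population, with 1 of 24 pairs above 0.1, and between -0.0846 and 0.129 across populations after the same antibody, with 1 of 12 above 0.1, and a library correlated best with its own number in 5 of 12 cases. With the replicate number as a block, 0 genes were called for anti-JAML against anti-PD-1 in CD8 cells (1 without it) and 0 for anti-PD-1 in Treg cells (3 without it), 1075 for CD8 against Treg cells and 0 elsewhere, and 97 list calls were kept and 2 lost.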

Other observations

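The tests in this part were chosen after the data were seen. Receptor segment genes gave a further difference between the populations. In CD8 libraries the largest share of Trav counts taken by 1 segment lay between 12.7% and 62.2%, and in Treg libraries between 6.94% and 12.1%, over 12 libraries each. The largest Trbv share lay between 16.4% and 47.4% in CD8 libraries and between 14.2% and 27.9% in Treg libraries. After isotype the largest Trbv share was 30.1 ± 6.90% in CD8 and 17.1 ± 1.31% in Treg libraries, and the largest Trav share 28.6 ± 17.9% and 9.99 ± 2.08% (SD, n = 4). After anti-PD-1 the Trav shares were 43.7 ± 17.7% and 10.006 ± 2.50%, and after anti-JAML 39.5 ± 18.7% and 9.90 ± 1.32%. Of 6 two-sided exact permutation tests of CD8 against Treg libraries, 5 gave p = 0.0286, the smallest that 4 against 4 can give (adjusted p = 0.0343). The Trbv test after anti-JAML gave p = 0.171, with 31.0 ± 12.7% against 19.4 ± 5.94% (exact, n = 4).

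Trbv13-2 had the largest Trbv share in 7 of 12 Treg libraries, where 4 different Trbv and 8 different Trav segments led. In CD8 libraries 9 different Trbv and 11 different Trav segments led. Near-identical copies among Trav segments can split reads, and each library held fewer than 400 cells.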
